A study of Caenorhabditis elegans with 4 samples.

How the data were processed

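Genomic binding of HPL-2 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in young adult Caenorhabditis elegans hermaphrodites of strain YL472. HPL-2 is a C. elegans homologue of heterochromatin protein HP1. The strain carries an extrachromosomal transgene, introduced by bombardment, in which a GFP- and FLAG-tagged HPL-2 is placed under the mex-5 promoter, a promoter used for germline expression, together with unc-119 as the rescuing marker. Reads from the transgene and from the matching native loci cannot be told apart, and which peaks lie at those loci was not determined here. Per the labels' protocols, worms were grown at 20 °C on E. coli HB101, crosslinked in formaldehyde at 2% and sonicated. An input sample of 10% of the supernatant was set aside, and the rest was precipitated with an affinity-purified goat antibody against GFP. The 4 samples are 2 ChIP and 2 input libraries, numbered 1 and 2 in each group by their titles, and these numbers are used throughout. The deposited ChIP lists are themselves named as replicates 2 and 3, and each was assigned to the library under which GEO holds it, so every value given for one replicate rests on that record. Nothing in the labels says whether the replicates came from separate cultures.

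The deposited values are peak lists, 1 for each ChIP library and 1 combined list for the series. Per the file headers the coordinates are those of WormBase build WS220, and the source field of each row names the peak caller SPP followed by IDR, a method that ranks peaks by their reproducibility between replicates. The aligner, the tool versions, the thresholds, the read depth and the way the replicates were combined are not given in the sources used here. The list of replicate 1 holds exactly 30000 peaks, a round number that a limit on list length would give. Its length and covered sequence may therefore not be measured extents, which could not be checked here. Each peak has a position and a score from the authors' deposited lists, and the scale of the score is not named. The score is the authors' own value and was used only to rank peaks within a list. Its highest value differs between the lists, so its levels were not compared across them, and the correlation between replicates uses only the order of the scores within each list. How the inputs entered the peak calling is likewise not given, and no input values were analysed here. Read depth is unknown, so no interval or detection limit that needs read counts is given, and the 95% intervals on shares of peaks are exact Clopper-Pearson intervals that cover the number of peaks only.

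The number in each peak's name served as its rank. In the replicate lists this number followed the score, with a Spearman rho of -1.00 in replicate 1 and in replicate 2 and a largest rise between neighbouring ranks of 0.000815 and 0.000512 score units. The number also orders the peaks tied at the highest score, which are 532 peaks in replicate 1 and 1865 in replicate 2. All 329 combined peaks have 1 score, so only their numbers rank them.

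Replicates were compared at matched length by taking the 329 best-ranked peaks of each, as many as the combined list holds. These are called the best peaks below. Peaks counted as shared when they overlapped by at least 1 bp. The combined list comes from the same ChIP libraries as the replicate lists, so its overlap with them was described and is not an independent test. Chance overlap came from 1000 random placements of 1 list within its chromosomes, tested one-sided, and the smallest p-value these 1000 allow is 0.001. Where overlap is given for the 100, 1000 and 10000 best peaks, chance came from 100 placements and no p-value is given. The chromosome shares of nuclear peaks were tested against the share of length by two-sided exact binomial tests, with Benjamini-Hochberg adjustment over the 6 chromosomes. The length of a chromosome was taken as the highest peak end on it in the 3 lists. For arms, each autosome was cut into 3 parts of equal length, and the outer parts, by peak midpoint, are the arms. Clustering was the share of peaks whose midpoint lies within 5 kb of another, against 1000 random placements. Shares of peaks in different lists were compared by Fisher's exact test, two-sided. These tests treat peaks as the units, and none of their p-values measures the spread between worm populations, for which there are only 2 ChIP libraries.

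The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The steps were tested on simulated lists of 329 peaks. In 50 simulations each, an overlap of 9.73% of peaks, an X share of 8% and a set of planted neighbouring peaks were detected in 100% of simulations. Lists with no such effect passed the 0.05 threshold in 2% of simulations for overlap, 2% for the X share and 8% for clustering. The simulated peaks were placed at random on nuclear chromosomes, with no mitochondrial peaks and no grouping beyond the planted one. These rates therefore check the steps and do not carry over to the real lists, which hold both.

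Alternatives covered the overlap rule, the number of peaks kept, the better-ranked 164 of the combined peaks, 1 replicate's list alone, merging of neighbouring peaks, the definition of arms, the clustering distance and the random placement. The tests of promoters, repeats and gene lists planned before the data were examined were not run, because the gene table at hand is on build WBcel235 and coordinates were not mixed between builds. For the same reason the named items are, by the rule fixed for this case, the 15 best-ranked combined peaks by coordinates, and the genes at these sites are not named here. Joined regions and dense windows named in addition were chosen after their values were seen.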

Results

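The ChIP-seq data give peaks of an immunoprecipitation of GFP-tagged HPL-2, an HP1 homologue expressed from a germline promoter, from young adult hermaphrodites. Replicate 1 held 30000 peaks and replicate 2 held 22864 peaks, and the combined list held 329. The round number in replicate 1 leaves open that its list was limited in length, in which case its extent was set by that limit. The peaks of each list had nearly uniform widths, which were 490 bp for 29976 peaks of replicate 1, 420 bp for 22843 peaks of replicate 2 and 636 bp for 314 combined peaks. After overlapping peaks were merged, the lists covered 13514 kb in replicate 1 (13.5% of the span of all sequences), 9163 kb in replicate 2 (9.14%) and 197 kb in the combined list (0.197%). The 2 input libraries have no values of their own here, so no background level is given beside the peaks, and the read depth is unknown.

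The first comparison asked whether the peaks of the ChIP replicates lay at the same positions. Random placement holds none of the background that 2 libraries can share. No input values were analysed, and the samples include no ChIP from worms without the tag. Overlap above chance therefore shows repeated positions and does not tell HPL-2 binding from shared background. Among the 329 best peaks, 95 peaks of replicate 1, or 28.9% (95% interval 24.04 to 34.1%), overlapped a best peak of replicate 2, against 4.74% under random placement (p = 0.001, permutation test, the smallest p that 1000 placements allow). In the other direction, 94 best peaks of replicate 2 (28.6%) overlapped a best peak of replicate 1. Of the 95 shared peaks, 19 lay on mitochondrial DNA and 76 on nuclear chromosomes, and 73 of the 76 nuclear ones also overlapped a combined peak. With mitochondrial peaks removed before the best were taken, the overlap was 24.6% against 0.345% by chance. When all peaks of the other replicate were allowed as partners, 83.0% of the best peaks of replicate 1 and 88.8% of those of replicate 2 had one, against 23.1% and 28.4% by chance. Over the full lists the overlap was 29.4% of replicate 1 peaks against 18.99% by chance. On nuclear chromosomes the overlap was 19% for the 100 best peaks of each list, 22.5% for the 1000 best and 23.9% for the 10000 best, and chance gave 0.09%, 1.01% and 8.98% over 100 random placements. With mitochondrial peaks kept, the overlap was 31%, 24.2% and 24.01% and chance gave 13.9%, 2.62% and 9.12%, because mitochondrial peaks were placed at random within 13422 bp. Across the 8818 replicate 1 peaks with a partner, Spearman's rho between the scores was 0.20 (95% bootstrap interval 0.18 to 0.22). This correlation is across peaks, which are not independent replicates.

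The combined list was compared with each replicate. All 329 combined peaks overlapped a peak of replicate 1, and 323 (98.2%, 95% interval 96.1 to 99.3%) overlapped a peak of replicate 2, where random placement gave 28.7% and 21.9%. The combined list was made from the same libraries, so a high overlap follows from its construction and no test is given. The 6 combined peaks without a partner in replicate 2 lay on X, I, II and IV. Of the combined peaks, 189 (57.4%) overlapped a best peak of replicate 1 and 160 (48.6%) a best peak of replicate 2. The best peaks of both replicates reached 79 combined peaks (24.01%), those of replicate 1 alone 110, those of replicate 2 alone 81, and those of neither 59. Among the 323 combined peaks with a partner in both, the median rank was 245 in replicate 1 and 343 in replicate 2, and 177 combined peaks were among the 1000 best of both.

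**Figure D1:**
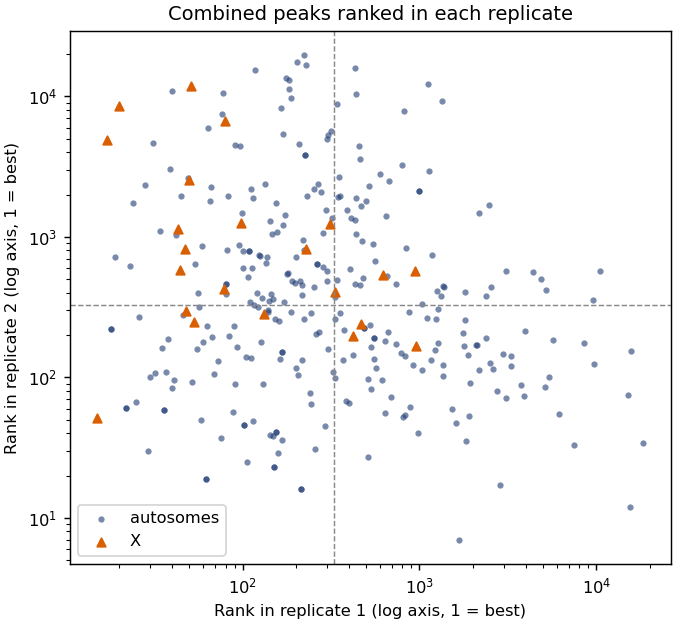
Rank of each of the 323 combined peaks with partners in both replicates, in replicate 1 (x axis) and replicate 2 (y axis), both on log axes with 1 as the best rank; triangles are X peaks, circles autosomal peaks, and dashed lines mark rank 329. The points spread on both sides of each line, with median ranks of 245 and 343.

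The 15 best-ranked combined peaks lay on all 6 nuclear chromosomes, and 12 of them were also reached by best peaks of both replicates. Combined peak 1 spanned 16963280 to 16963891 on chromosome V and ranked 7 in replicate 2 but 1677 in replicate 1. Combined peak 2, at 11093824 to 11094459, was the best site on X and ranked 15 and 51 in replicates 1 and 2. On chromosome IV, combined peak 3 spanned 7083320 to 7083498 (ranks 62 and 19) and combined peak 12 spanned 1710891 to 1711526 (ranks 167 and 36). Chromosome III held 5 of the 15. Combined peak 4 spanned 1419669 to 1419904 (ranks 58 and 50), combined peak 5 spanned 1618816 to 1619451 (ranks 32 and 108), and combined peak 9 spanned 3867435 to 3867719 (ranks 30 and 101). Further along III, combined peak 14 spanned 10758841 to 10759476 (ranks 19 and 714) and combined peak 15 spanned 4015582 to 4015932 (ranks 29 and 30). Chromosome I held combined peak 6 at 5620300 to 5620935 (ranks 149 and 38), combined peak 10 at 4645176 to 4645811 (ranks 106 and 25) and combined peak 13 at 13953143 to 13953516 (ranks 69 and 105). Chromosome II held combined peak 7 at 4702878 to 4703513 (ranks 509 and 27) and the overlapping combined peaks 8 and 11 at 5844496 to 5845131 and 5844708 to 5845343, both matched by the peaks ranked 18 and 221. All positions are in WS220, and the annotation at these sites was not used here. Whether any of them lies at a native locus of the transgene's parts (hpl-2, mex-5 or unc-119), where reads from the transgene would add to the peak, was not determined.

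The next comparison asked how the peaks were distributed over the chromosomes. Combined peaks were scarce on X and frequent on chromosomes III and I. X held 24 of the 329 combined peaks, or 7.29% (95% interval 4.73 to 10.7%), where its length predicts 17.7%, a ratio of 0.413 (adjusted p = 4.05e-07, exact binomial test). Chromosome III held 75 peaks, 1.66 times its length share (95% interval 1.34 to 2.02, adjusted p = 2.67e-05), and chromosome I held 71, 1.44 times its length share (1.15 to 1.76, adjusted p = 0.00298, exact binomial tests). Chromosome V, the longest, held 49 peaks, 0.714 times its length share (0.538 to 0.920, adjusted p = 0.00989, exact binomial test). Chromosomes II and IV, with 51 and 59 peaks, were at 1.02 (0.772 to 1.30) and 1.03 (0.799 to 1.29) times their length share and did not pass the test. In peaks per Mb, the density went from 1.35 on X to 5.44 on III.

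**Figure D2:**
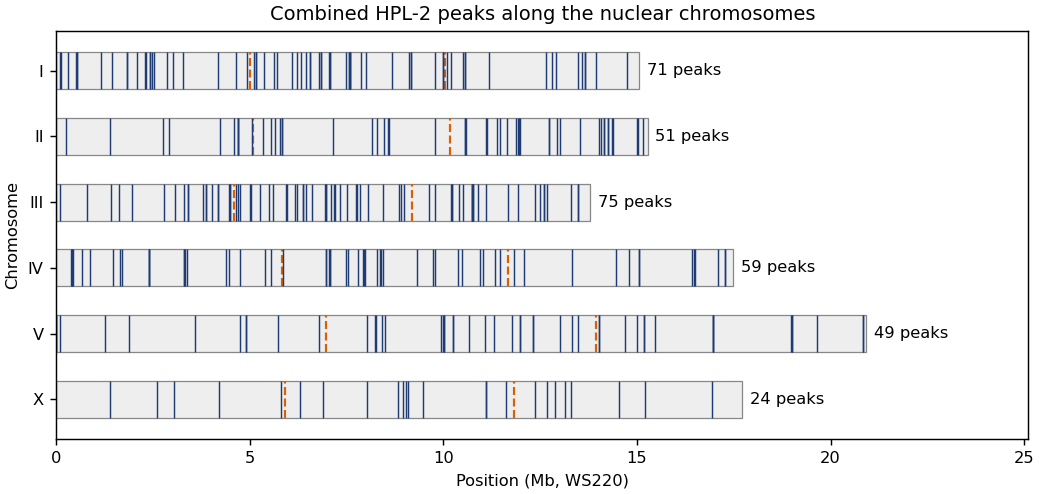
Positions of the 329 combined peaks (vertical lines) along the 6 nuclear chromosomes in Mb of build WS220, with dashed lines that cut each chromosome into 3 equal parts. Chromosome III carries 75 peaks and X carries 24.

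The replicates were then examined one by one. Among the nuclear best peaks, chromosome I was at 1.60 times its length share in replicate 1 and 1.63 in replicate 2, chromosome III at 1.61 and 1.69, and X at 0.569 (95% interval 0.393 to 0.791) and 0.166 (0.0766 to 0.312). Each of these passed the exact binomial test in both replicates, with a largest adjusted p of 0.000477. Chromosome V was at 0.716 (adjusted p = 0.0141) in replicate 1 and 0.767 (adjusted p = 0.0524) in replicate 2, so its shortfall passed the exact binomial test in replicate 1 and not in replicate 2. The X share itself differed between the replicates, with 31 of 308 nuclear best peaks in replicate 1 (10.1%) and 9 of 306 in replicate 2 (2.94%; p = 0.00045, Fisher's exact test). All best peaks of each list share its highest score, so this contrast rests on the numbers that order tied peaks. Over all nuclear peaks at the highest score, X held 50 of 511 in replicate 1 (9.78%) and 147 of 1840 in replicate 2 (7.99%). The size of the X shortfall among the best peaks is therefore known less closely than either interval.

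**Figure D3:**
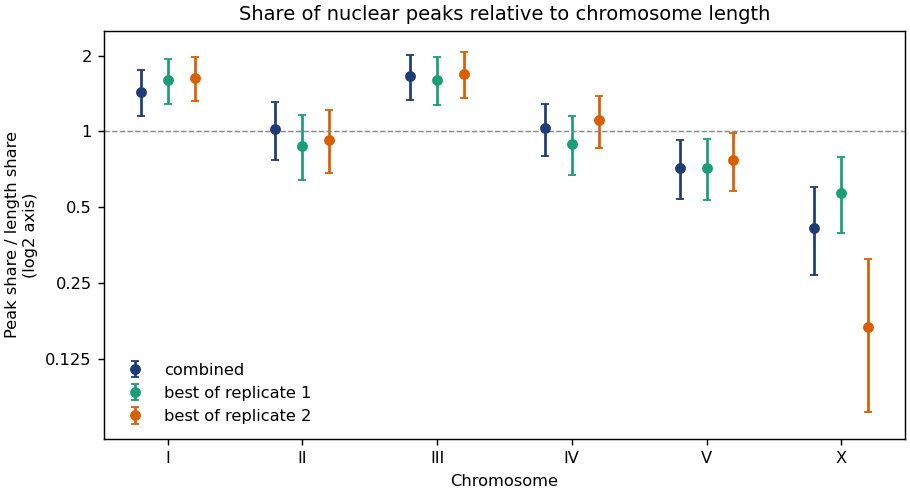
Share of nuclear peaks on each chromosome divided by its share of length (log2 axis) for the combined list and the best peaks of each replicate; bars are 95% exact binomial intervals and the dashed line marks 1. X lies at 0.413 in the combined list, 0.569 in replicate 1 and 0.166 in replicate 2.

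Within each replicate list, the chromosome shares of the best peaks were compared with those of the remaining peaks. In replicate 1 the X share was 10.1% of the best peaks, 9.40% at ranks 330 to 1000, 12.5% at ranks 1001 to 5000 and 15.7% beyond rank 10000. In replicate 2 it was 2.94%, 7.32%, 11.3% and 15.3% over the same ranks. Best peaks lay on X less often than the remaining peaks in replicate 1 (10.1% against 14.9%, p = 0.0156) and in replicate 2 (2.94% against 14.2%, p = 7.38e-11, Fisher's exact tests). They lay more often on I (24.03% against 16.9%, p = 0.0013 in replicate 1, and 24.5% against 17.6%, p = 0.00246 in replicate 2, Fisher's exact tests). The same was found for III (22.1% against 16.18%, p = 0.00807 in replicate 1, and 23.2% against 16.7%, p = 0.00424 in replicate 2, Fisher's exact tests). Within the combined list, X held 16 of the better-ranked 164 peaks (9.76%) and 8 of the other 165 (4.85%), the opposite order to the replicate lists, and the difference did not pass the test (p = 0.0944, adjusted over 3 chromosomes 0.283, Fisher's exact test). Chromosome I held 31 and 40 of these peaks (18.9% and 24.2%, adjusted p = 0.426) and III held 39 and 36 (23.8% and 21.8%, adjusted p = 0.695, Fisher's exact tests). Beyond rank 10000 of the replicate lists, X was still at 0.886 of its length share in replicate 1 and 0.865 in replicate 2.

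**Figure D4:**
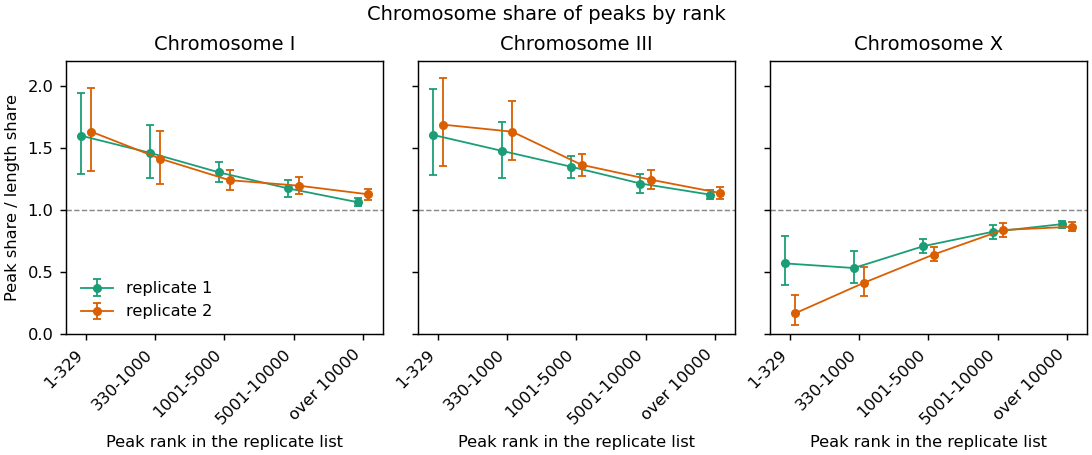
Peak share over length share of chromosomes I, III and X (y axis) by peak rank in each replicate list (x axis), with 95% exact binomial intervals; the dashed line marks 1. Values lie closest to 1 beyond rank 10000, and X goes from 0.569 to 0.886 in replicate 1 and from 0.166 to 0.865 in replicate 2.

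Arms and centres of the autosomes were compared because autosome arms carry most of the H3K9 methylation in C. elegans, the mark that HP1 proteins bind. Of 305 autosomal combined peaks, 180 lay in the arms, the outer parts when each autosome is cut into 3 of equal length, 59.0% (95% interval 53.3 to 64.6%) against 66.7% expected from length (p = 0.00518, exact binomial test). The share was 59.9% in the best peaks of replicate 1 (p = 0.0184) and 59.6% in those of replicate 2 (p = 0.0115, exact binomial tests). Chromosome I had 53.5% of its peaks in the arms and II had 74.5%, and no single chromosome passed the exact binomial test after adjustment (lowest adjusted p = 0.138). Among the autosomal peaks in the better-ranked 164 of the combined list, the arm share was 64.2% and no longer differed from expectation by the exact binomial test (p = 0.542). The full list of replicate 1 had an arm share of 66.6% and that of replicate 2 had 64.2%.

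The last comparison asked whether peaks stood singly or in groups. Of the combined peaks, 78 (23.7%, 95% interval 19.2 to 28.7%) had another combined peak within 5 kb, against 3.71% under random placement (p = 0.001, permutation test). Among the nuclear best peaks the share was 16.6% in replicate 1 and 26.8% in replicate 2, against 3.46% and 3.68%. Overlapping calls made up part of it, since 40 combined peaks overlapped another, and after these were merged 39 of 309 regions (12.6%) had a neighbour within 5 kb, against 3.51% by chance. Joining peaks closer than 5 kb gave 287 regions, of which 247 held 1 peak, 38 held 2 and 2 held 3. The longest was 6215 bp. The regions of 3 peaks spanned 16960059 to 16965700 on V and 4701080 to 4703513 on II. The 3 peaks on V ranked 7, 17 and 12 in replicate 2 but 1677, 2838 and 15455 in replicate 1. On II, 2 of the 3 peaks overlapped each other.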

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

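The tests of X and of chromosome III below were chosen after the results were seen, and the prediction for the mitochondrial test was written before its result.

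Mitochondrial peaks stood out because they head both replicate lists and are outside every comparison of chromosomes. Replicate 1 held 27 mitochondrial peaks and replicate 2 held 26, and the combined list held 0. In each replicate 15 of the 20 best-ranked peaks were mitochondrial, and the peaks covered 58.0% and 51.4% of the 13422 bp spanned. Even coverage of a high-copy DNA, with positions set by chance, was tested by matching positions: 57.7% of replicate 2 midpoints lay within 100 bp of a replicate 1 midpoint, against 34.1% under random placement (p = 0.017, permutation test). This argues against chance positions. The other part of the prediction for even coverage, that peaks cover most of the spanned sequence, held at 58.0% and 51.4%. Uneven coverage that repeats between libraries, through sequence composition or fragmentation, stays open, and no biological explanation was tested.

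The shortage of combined peaks on X was weighed against a lack of callable sequence. If X offered fewer sites at every rank alike, its share would be equal among best and remaining peaks, but it was lower among the best peaks in both replicates (larger p = 0.0156, smaller p = 7.38e-11, Fisher's exact tests). Against the X share of all replicate peaks in place of length, the ratio was 0.502 (95% interval 0.326 to 0.734). In the full lists X was at 0.841 of its length share in replicate 1 and 0.797 in replicate 2. Part of the shortage was therefore already present there, and the test speaks only to equal scarcity as the whole source. Within the combined list the order was opposite, with 16 of the better-ranked 164 peaks on X and 8 of the other 165. That difference did not pass (p = 0.0944, Fisher's exact test). A lower read depth on X could lower the best ranks more than the others, and it stays open because no read depths were analysed here. The design has no contrast that would test a biological explanation.

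The excess on chromosome III was weighed against a few dense windows. Without the 3 densest 100 kb windows of III, which held 11 combined peaks, III was still at 1.49 times its length share (95% interval 1.18 to 1.85). The fullest of these windows held 5 of the 75 combined peaks on III, which was known when the test was chosen. The outcome was therefore largely set beforehand, and it describes an excess not confined to these windows. A multicopy transgene array would add reads at the native loci of its parts. Those loci were not located here, so the test does not address an array. Against the share of all replicate peaks in place of length, III was at 1.38 (95% interval 1.11 to 1.68). Chromosome I was at 1.25 on that basis (95% interval 1.0003 to 1.53). Part of each excess was therefore already present in the full replicate lists. A difference in gene content between chromosomes stays open and was not tested, since no annotation of build WS220 was used.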

How the results depend on the processing

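Of the results under the alternatives run, the replicate overlap, the X shortfall, the excess on III and the clustering kept their direction and stayed past the threshold, under 7, 7, 5 and 8 alternatives. The replicate overlap was between 21.3% (reciprocal overlap of 50%) and 43.8% (all peaks at each list's highest score). The 43.8% sets 532 peaks of replicate 1 against 1865 of replicate 2, so its list lengths are not matched. A longer partner list raises the overlap. The share of combined peaks found in both replicates, which its construction keeps above chance, moved most, from 24.01% with the best peaks to 52.9% with all peaks at the highest score and 98.2% with any peak. With the best peaks of 1 replicate alone, the combined list unchanged, the share was 48.6% for replicate 2 and 57.4% for replicate 1. The X share was 2.94% in the nuclear best peaks of replicate 2 and 10.1% in those of replicate 1. In the better-ranked 164 of the combined peaks it was 9.76%. Over all nuclear peaks at each list's highest score it was 9.78% in replicate 1 and 7.99% in replicate 2. The low value of replicate 2 thus depends on the cut at 329 among tied peaks. Clustering fell to 10.2% once peaks within 1 kb were merged. Among those 164, the arm share of 64.2% (p = 0.542) and the chromosome I share of 18.9% (p = 0.188) no longer passed the exact binomial test, with 148 of the peaks on autosomes. The cause was not tested. Rank agreement moved to 0.23 for midpoints within 200 bp. Rank numbers in place of scores gave 0.21 over all peaks, and 0.40 and 0.32 when the lists were also limited to the 329 and 1000 best. Of the 95 pairs behind the 0.40, 19 were mitochondrial peaks, which head both lists and can raise this value. No value for nuclear pairs alone is given for these best peaks, so their agreement on nuclear sites stays unknown. The planned score correlations for the 329 and 1000 best peaks could not be computed because of tied scores. The 329 best of both replicates, and the 1000 best of replicate 2, are all at the highest score of their list. Alternatives on highest scores, nuclear peaks only, overlap-merged peaks, rank numbers, shares of all replicate peaks, and all those for chromosomes I and III were added after seeing the data. The alternatives set beforehand for promoters, repeats and gene lists were not run, as no annotation of build WS220 was used. No paired analysis was possible because no input values were analysed here and each replicate number is held by 1 ChIP list. Depth limits are unknown without read counts.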

Other observations

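The tests in this part were chosen after the results were seen. Of the 24 combined peaks on X, 18 (75%) overlapped a best peak of replicate 1 and 7 (29.2%) a best peak of replicate 2, while of the 305 autosomal combined peaks 171 (56.1%) and 153 (50.2%) did. The difference between X and autosomes did not pass 0.05 in either replicate (p = 0.0868 and p = 0.0567, Fisher's exact tests). Over the 22 X peaks with partners in both replicates, the median rank was 78.5 in replicate 1 and 575.5 in replicate 2, against 261 and 315 for the 301 such autosomal peaks. These medians all lie among peaks tied at the highest score, which are the first 532 ranks of replicate 1 and the first 1865 of replicate 2. They therefore show no difference in score. Ranks also come from lists of different length, and the difference between the replicates in these ranks was not tested. Of the 6 combined peaks without a partner in replicate 2, 2 lay on X, at 13145077 to 13145712 and 1389251 to 1389886.

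The 329 combined peaks fell into 241 of the 1005 windows of 100 kb. The fullest windows held 5 peaks each, from 10700001 to 10800000 on III and from 7500001 to 7600000 on I. Window counts and their p-value take overlapping peaks as separate. Such peaks lay at 10746119 to 10746959 on III, and at 7559478 to 7560384 and 7585035 to 7585988 on I. Whether either window holds a native locus of the transgene's parts, to which reads from the transgene would map, was not determined. Random placement within chromosomes gave a fullest window of 5 or more with p = 0.0629 (permutation test), so a maximum of 5 did not pass the threshold. On the 1 Mb scale, 7 to 8 Mb of I and 10 to 11 Mb of III held 11 combined peaks each.

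A group of 39 combined peaks ranked worse than 5000 in one replicate, 14 of them in replicate 1 and 25 in replicate 2. Of these, 37 were among the 1000 best of the other replicate, and 0 ranked worse than 5000 in both.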
